A study of Homo sapiens with 2 samples.

How the data were processed

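The data were 2 RNA-seq libraries of NCI-H2030, a human lung adenocarcinoma cell line. Per the labels, 1 culture was treated with SC and 1 with miR-494-3p AS, and the labels spell out neither abbreviation. The groups are called SC and AS here. Per the labels' protocols, total RNA was isolated with a silica column kit and libraries were made with a directional kit, which keeps the strand of the transcript. With 1 library in each group there were no replicates, so no test, p-value, standard error or spread between replicates was computed, and every difference is one between these 2 libraries.

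The authors deposited 1 table per library with a coverage, an FPKM and a TPM column, per the file headers. The aligner and quantification program are not given in the sources used here. The row identifiers and column layout are those of a table of annotated genes and of loci assembled from the reads. The SC table held 57789 rows of annotated genes and 24269 rows of assembled loci, and the AS file held 57787 and 24627 of them. In the deposited TPM column the assembled loci summed to 1000000 in each library and the annotated genes to 973681 in SC and 968917 in AS. The 2 kinds of row were on 1 scale. CTGF, for example, had the same TPM in both, at 49.7 in SC and 122 in AS. The deposited FPKM column differed from the TPM column by 1 constant per library, 1.98 in SC and 2.13 in AS. In 54.6% of the SC rows and 52.6% of the AS rows above 0, the deposited coverage was, within 1%, 1 constant times the FPKM. That constant was 3.62 in SC and 3.54 in AS, which by the definition of FPKM is proportional to the aligned bases of the library. Read length and read counts are not given in the sources used here, so no counting interval was computed. In genes with several transcripts the coverage and the FPKM need not move together, because a program that divides reads among transcripts can move a gene's FPKM with no change in its reads.

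The submitters' processing notes name the builds GRCh38 and hg38, whereas the coordinates in both tables are those of GRCh37. Coordinates are printed as the tables give them. GENCODE release 29 was used by gene identifier for gene type, transcript sequence, GC content, transcript length and 3' UTR, and none of its coordinates were used. Of the measured genes, 95.9% had a GC content from it.

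The main measure was log2((AS + 1)/(SC + 1)) on the deposited TPM of annotated genes, with rows of 1 symbol summed. On this scale the ratio of a gene of low level is understated. A gene was measured if its mean over both libraries was at least 1 TPM, and genes at or past a log2 ratio of 1 in either direction were counted. The rule for the named genes was fixed before the data were examined, but many of these genes were picked by their observed ratios. They were the 12 protein coding genes with the largest and the 12 with the smallest ratio among those of at least 5 TPM in 1 library, SET, members of the list of described miR-494-3p targets, and in each gene list the 4 members with the largest absolute ratio. Some genes that this rule names are not reported here. Genes named outside this rule are marked as chosen after their values were seen. Values of named genes are in TPM unless another measure is named.

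The 37 gene lists were fixed before the data were examined and held 743 members, of which 741 matched a row. For each list with at least 5 measured members, the median log2 ratio minus the median of all measured genes was compared with 10000 random lists of the same size matched on mean level in 20 bins. A list outside the central 95% of random lists is called apart, as a description of these libraries. Because the log2 ratio followed the GC content of the transcript, each list was also compared with 10000 lists drawn from the 200 protein coding genes nearest to each member in GC content, length and level, a choice made after the data were seen. Further measures were added at the same time. They were the coverage column, with 0.1 added before the ratio, and the TPM of the largest assembled locus that best overlapped the gene. Coverage was divided by the coverage per FPKM of its library and multiplied by the TPM per FPKM, 1.98 in SC and 2.13 in AS. The multiplication put coverage on the TPM scale and raised its AS over SC ratios.

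The mature sequence of miR-494-3p, UGAAACAUACACGGGAAACCUC, was supplied from general knowledge. Positions 2 to 8 set the sites searched in the longest annotated 3' UTR of each gene. These were the 8-base site ATGTTTCA and the 7-base sites ATGTTTC and TGTTTCA. The shift between genes with and without a site was compared with 10000 reassignments within bins of level and 3' UTR length, and with the 210 7-base sequences of the same base composition.

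The alternatives tried were other pseudocounts, filters, scalings, gene sets, bins and matchings. The calculations were tested on simulated libraries of 10766 protein coding genes. Of the genes raised 4-fold, 99% were recovered with no GC trend. With a simulated GC trend, 84 of 100 unchanged lists of low GC content were called apart under matching on level, and 7 of 100 under matching on GC content, length and level. Without the trend these counts were 4 and 9. The simulated trend was built on the same GC content that the matching used, so the matching was bound to remove most of it. The simulated noise was of the same size at every level and independent between genes, and every changed gene had at least 5 TPM. These rates need not hold in the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. Reads shared among near-identical copies, such as ribosomal protein genes, heat shock genes and the pair MZT2A and MZT2B, could be divided differently in the 2 libraries, so values of such genes are uncertain.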

Results

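Transcript levels were compared between 1 NCI-H2030 library treated with SC and 1 treated with miR-494-3p AS. The title of the series names the microRNA miR-494-3p and SET, an inhibitor of protein phosphatase 2A (PP2A) also known as I2PP2A, so the comparison addresses how the lung adenocarcinoma transcriptome differs with a treatment directed at this microRNA. There were no replicates. The libraries were of similar depth, with a coverage per unit of FPKM of 3.62 in SC and 3.54 in AS, a measure of aligned bases. In SC 12816 genes reached 1 TPM, and in AS 14177. Mitochondrial transcripts made up 14.6% of annotated TPM in SC and 16.2% in AS. The gene of the microRNA itself, MIR494, was listed at 0 in both libraries; its mature form is not measured by these libraries, so the treatment could not be checked on its target.

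More transcripts were higher than lower in AS. Of 13669 measured genes, 2251 were at least 2-fold higher and 297 at least 2-fold lower in AS than in SC, so that 88.3% of these genes were higher. The median log2 ratio of all measured genes was 0.28 rather than 0. After centring on that median the higher share was 64.3% (1253 genes higher, 696 lower), and after trimmed mean scaling, which moved the ratios by 0.35, it was 55.5% (1067 higher, 855 lower). Ratios of gene lists are given relative to the median of all genes below. Of the genes past 2-fold, 1184 higher and 107 lower genes were also past 2-fold in both the coverage column and the assembled loci.

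The largest ratio in the main measure belonged to MATR3, a nuclear matrix protein that binds RNA (ENSG00000015479, chromosome 5, 138609441 to 138667360, GRCh37), with 1.65 TPM in SC and 50.4 TPM in AS, a log2 ratio of 4.28. Its log2 ratio was 2.27 in the coverage column and 2.08 in the assembled locus. It was followed by DDX10, an RNA helicase of ribosome assembly (0.774 and 23.3 TPM, log2 ratio 3.78), SLC25A12, the mitochondrial aspartate and glutamate carrier (3.72), DYM (3.59), NUCB2 (3.56), PTPN12, a tyrosine phosphatase (3.47), CDH2, the mesenchymal cadherin N-cadherin (0.157 and 11.8 TPM, 3.46), STT3B, a catalytic subunit of the oligosaccharyltransferase (3.45), NFATC3 (3.44), STK3, a kinase of the Hippo pathway (3.44), MKLN1 (3.37) and DNM1L, which divides mitochondria (3.30). All 12 were also higher in the coverage column, 9 of them at least 2-fold. Their median log2 ratio was only 1.14 there, against 3.47 in TPM. Their median GC content was 40.9%, and coding genes of 39.5% to 42.1% GC content had a median of 0.96 in coverage. Among its nearest genes in GC content, length and level, MATR3 lay at percentile 98.5 in coverage. The others lay between percentiles 29.5 (NUCB2) and 82 (NFATC3), so their coverage ratios were not unusual for such genes. Only 5 of the 12 were past 2-fold in TPM, coverage and assembled loci together. Their order depends on the pseudocount. At 0.1, STK3 (5.74), CDH2 (5.53), SLC25A12 (5.39) and MKLN1 (4.93) had larger ratios than MATR3 (4.85).

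The smallest ratios came from SFT2D3 (ENSG00000173349, chromosome 2, 128458597 to 128461385), at 7.07 TPM in SC and listed at 0 in AS, and BCAS3, with 6.12 and 0.141 TPM (log2 ratio -2.64). MZT2A, a component of the gamma-tubulin complex, stood at 283 and 47.3 TPM (-2.56). Others among the 12 genes with the smallest ratios were EXTL3 (-2.38), CCDC92 (-2.29), HSD17B7, an enzyme of cholesterol synthesis (-2.11), TSPAN14 (-2.10), ACAP1 (-2.09), USP20, a deubiquitinase (-1.93), ME3, the mitochondrial malic enzyme (-1.87) and ARHGAP22 (-1.82). The coverage column did not bear out most of these values. Its median log2 ratio over the 12 genes was -0.29, only 1 gene (SFT2D3) was 2-fold lower there, and it was 0.05 for MZT2A, 0.02 for EXTL3 and -0.01 for BCAS3.

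**Figure D1:**
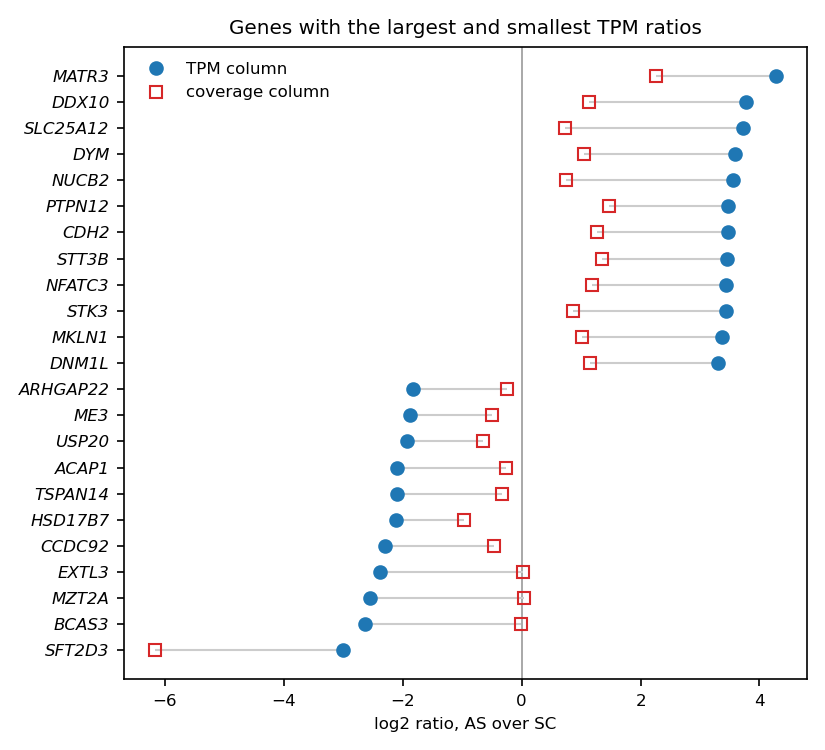
Log2 ratio of AS over SC for the 12 protein coding genes with the largest ratio in the TPM column and 11 of the 12 with the smallest (filled circles), with the same genes in the coverage column (open squares). In the coverage column the median log2 ratio was 1.14 for the 12 higher genes and -0.29 for all 12 lower genes; SFT2D3 was listed at 0 in AS, so its points depend on the pseudocount.

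The log2 ratio followed the base composition of the transcript. Among 10766 protein coding genes, the tenth with the lowest GC content (29.6% to 39.5%) had a median log2 ratio of 0.90 and the tenth with the highest (63.1% to 74.2%) one of -0.29. In the lowest group 42.5% of genes were at least 2-fold higher in AS, and in the highest 0.651%. Across genes, which are not independent replicates, Spearman's rho between GC content and log2 ratio was -0.64 in TPM, -0.70 in coverage and -0.57 in the assembled loci. Longer transcripts also had higher ratios, with a rho of 0.30 that was 0.15 given GC content. GC content is therefore given beside the lists that were apart under matching on level and beside some others below, against a median of 50.9% over the measured coding genes.

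**Figure D2:**
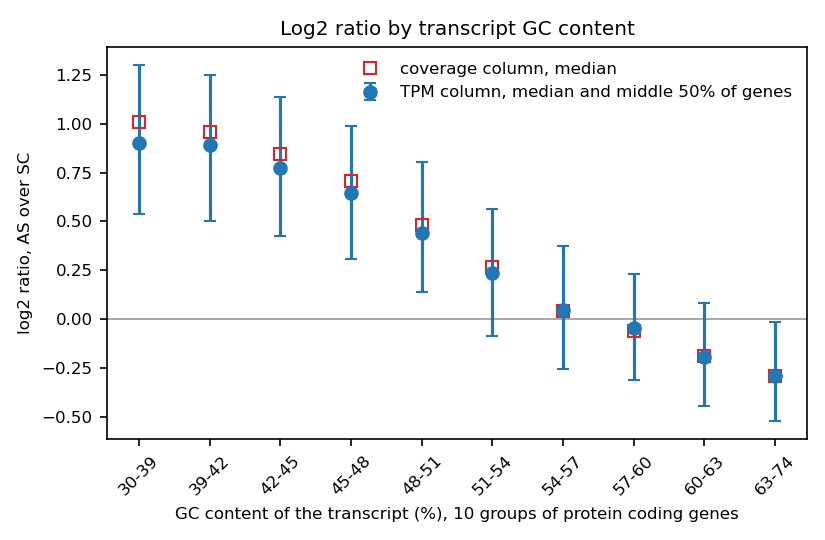
Median log2 ratio of AS over SC for 10 groups of protein coding genes of increasing transcript GC content, in the TPM column (filled circles, with bars for the interquartile range of genes) and in the coverage column (open squares). The medians ran from 0.90 at the lowest GC content to -0.29 at the highest in TPM, and from 1.01 to -0.29 in coverage.

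SET (ENSG00000119335, chromosome 9, 131445703 to 131458679, plus strand, GRCh37) was higher in AS, at 79.1 TPM against 30.4 TPM in SC, a log2 ratio of 1.35 or 2.55-fold. The ratio was 1.37 in the coverage column and 1.35 in the assembled locus. The 19 rows of SET pseudogenes and of the related gene SETSIP summed to 1.01 TPM in SC and 0.938 TPM in AS. SET transcripts have a GC content of 44.3%. The 200 genes nearest to SET in GC content, length and level had a median log2 ratio of 0.71, and SET lay at percentile 94.5 of them, inside their central 95% of -0.18 to 1.55. The longest annotated 3' UTR of SET, of 1736 bases, held 1 seed match of miR-494-3p, the 7-base site TGTTTCA at bases 779 to 785 of the UTR, within ATTTTCTTTTTGTTTCACTGGAAAGGA.

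Genes described as targets of miR-494-3p, SET among them, were not apart from random lists with the main measure. Of the 14 measured members of that list (median GC content 46.7%), 6 were at least 2-fold higher, none was 2-fold lower and 8 lay between. PTPN12 stood at 0.639 and 17.1 TPM, BMI1, a Polycomb protein, at 1.80 and 11.1 TPM (log2 ratio 2.11), BCL2L11, the apoptosis activator BIM, at 0.327 and 4.43 TPM (2.03), CASP2 at 2.01 and 6.42 TPM (1.30), and CDK6 at 1.24 and 3.51 TPM (1.01). For PTPN12 the assembled locus was at 6.86 TPM in SC and 17.1 TPM in AS, and the log2 ratio in coverage was 1.47. MYC was at 22.0 and 26.0 TPM (0.24). The list median was 0.47 above that of all genes, at percentile 95.8 of lists matched on level, and 0.20 above that of lists matched on GC content, length and level (percentile 84.8). The list was apart with a pseudocount of 0.1 (0.70), as a mean of its members (0.63) and in the assembled loci (0.86).

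Few genes of PP2A itself passed 2-fold. Among 16 measured subunits, 1 was at least 2-fold higher and 15 lay within 2-fold. The catalytic subunit PPP2CA was at 34.8 TPM in AS (log2 ratio 1.25), PPP2CB at 15.8 and 31.5 TPM (0.95), and PPP2R3C and PPP2R5E had log2 ratios of 0.92 and 0.90. The list median was 0.20 above all genes (percentile 91.5; GC content 45.4%) in TPM and 0.47 above in the coverage column (percentile 99.55), where it was apart from lists matched on level but not from those matched on GC content, length and level (0.32, percentile 95.4). Among 13 modulators of PP2A, 4 were at least 2-fold higher and none lower. These were BOD1, a PP2A inhibitor of the kinetochore (29.5 and 83.4 TPM, 1.47), KIAA1524, which encodes the inhibitor CIP2A (1.34), ANP32E (1.26) and TIPRL (1.07). BOD1 lay at percentile 99.5 of its 200 nearest genes. With the main measure the modulator list as a whole was not apart, at 0.16 above all genes (percentile 93.9) and -0.09 relative to lists matched on GC content, length and level (percentile 34.0); it was apart with a pseudocount of 5 (0.24). Of 13 measured genes of the microRNA machinery, 2 were 2-fold higher, TNRC6B (0.193 and 3.31 TPM, 1.85) and XRN2 (1.30), ahead of DGCR8 (0.94) and AGO1 (0.75). That list was not apart either (0.23, percentile 71.1). Of the transcripts of the 14q32 region that holds the miR-494 gene, 2 of 9 were measured, DIO3OS (log2 ratio 0.27) and DIO3 (-0.26).

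Genes with a seed match of miR-494-3p in the 3' UTR had higher ratios than genes with none. The median log2 ratio was 0.63 for 3048 genes with a 7-base or 8-base site and 0.18 for 7635 genes without, a shift of 0.45. Reassignments matched on level and 3' UTR length gave a median shift of 0.26, with a central 95% of 0.24 to 0.28, below the observed value in all 10000. After matching on 3' UTR GC content as well, the reassigned shift was 0.42 and the observed one was 0.02 larger, at percentile 98.8. Among the 210 7-base sequences with the same composition, ATGTTTC lay at percentile 74.6 and TGTTTCA at percentile 88.0.

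Cell cycle genes were higher in AS. Of 25 G2/M genes, 12 were at least 2-fold higher and none was 2-fold lower. HMMR stood at 4.20 and 23.7 TPM (log2 ratio 2.24), CDK1, the mitotic kinase, at 9.86 and 33.7 TPM (1.67), and the mitotic kinesins KIF23 and KIF11 had log2 ratios of 1.40 and 1.28. The list median was 0.70 above all genes, above all 10000 lists matched on level. These are genes of low GC content (median 42.6%), and relative to lists matched on GC content, length and level the median was 0.31 higher (percentile 98.3), with 20 of 25 members above the median of their nearest genes. Of 24 measured G1/S genes, 9 were 2-fold higher and none lower. They were led by POLA1, a subunit of DNA polymerase alpha (2.78 and 12.4 TPM, 1.83), MCM10 (1.81), SLBP, the histone stem-loop binding protein (1.48) and RRM1, a subunit of ribonucleotide reductase (33.3 and 87.5 TPM, 1.37). With a GC content of 50.7%, this list was 0.45 above all genes (percentile 99.99) and 0.43 above lists matched on GC content, length and level (percentile 99.9).

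The lists of MYC targets and of YAP and TAZ targets were also higher. Of 22 MYC targets, 7 were 2-fold higher and none lower. POLR1B, a subunit of RNA polymerase I, was at 1.17 and 11.5 TPM (log2 ratio 2.53), the transferrin receptor TFRC at 7.46 and 37.7 TPM (2.19), WDR43 had a log2 ratio of 1.47 and NOLC1 one of 1.37. The list was 0.22 above all genes (percentile 99.98; GC content 51.2%) and 0.34 above lists matched on GC content, length and level (percentile 99.1). Of 20 measured YAP and TAZ targets, 3 were 2-fold higher and 17 within 2-fold. The named members were CTGF, a matricellular protein (49.7 and 122 TPM, 1.28), TEAD1, the DNA-binding partner of YAP (1.26), AMOTL2 (1.06) and NUAK2 (0.95). The list median was 0.58 above all genes (percentile 99.9; GC content 51.5%) and 0.50 above lists matched on GC content, length and level (percentile 99.97), although its mean lay within the central 95% of lists matched on level (0.34, percentile 97.0). The 13 messenger RNAs of the mitochondrial genome were all within 2-fold, led by MT-ATP8 (0.68), MT-ND4L (0.53), MT-ND5 (0.47) and MT-ATP6 (0.46). Their median lay at -0.01 relative to all genes, which was at percentile 99.6 of lists from the bins of highest level, whose genes are mostly less abundant than these, and 0.30 above lists matched on GC content, length and level (percentile 98.1; GC content 44.3%).

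The list of cholesterol synthesis and the list of hypoxia and glycolysis were lower in AS. Of 22 measured SREBF2 targets of the cholesterol pathway, 4 were at least 2-fold lower, 3 at least 2-fold higher and 15 within 2-fold. The lower members included HSD17B7 (15.1 and 2.71 TPM), MVD, the mevalonate diphosphate decarboxylase (335 and 110 TPM, log2 ratio -1.59), and TM7SF2, a sterol reductase (84.5 and 37.7 TPM, -1.14), whereas SC5D was higher (3.18 TPM in SC, 1.40). For HSD17B7 the log2 ratio was -0.97 in coverage and -1.17 in the assembled locus. The list median was -0.66 relative to all genes (percentile 0.020; GC content 49.4%) and -0.69 relative to lists matched on GC content, length and level, below all 10000, with 18 of 22 members under the median of their nearest genes. In the coverage column all 22 members were under the median of their nearest genes. Of 29 measured hypoxia and glycolysis genes, 4 were 2-fold lower and 2 higher. The lower ones were ANGPTL4, a secreted lipase inhibitor induced by HIF (402 and 140 TPM, -1.51), the glycolytic enzymes ENO2 (37.4 and 16.1 TPM, -1.17) and ALDOC (211 and 98.5 TPM, -1.09), and the lactate transporter SLC16A3 (115 and 53.2 TPM, -1.10). The list median was -0.64 relative to all genes and -0.42 relative to lists matched on GC content, length and level, below all 10000 lists in both cases (GC content 55.3%). Among 13 measured genes of fatty acid synthesis, FASN, the fatty acid synthase, was at 219 and 81.8 TPM (-1.41), and ACSL3 (1.83), ACSL4 (0.90) and ACACA (0.89) were higher. That list was not apart from lists matched on level (-0.16, percentile 59.1) but was lower than lists matched on GC content, length and level (-0.38, percentile 1.53), a call that ended in the assembled loci (-0.33, percentile 2.97).

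**Figure D3:**
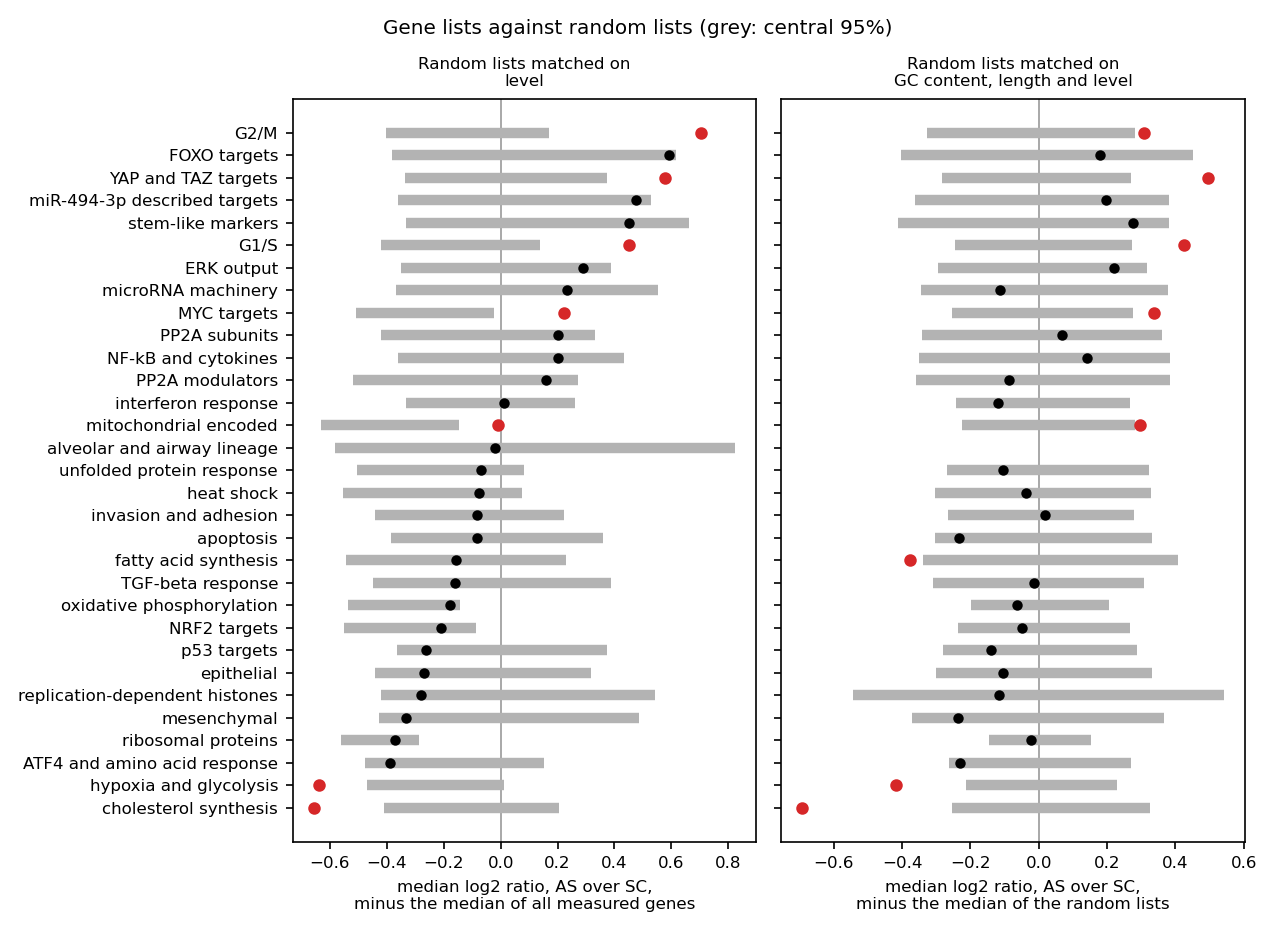
Median log2 ratio of AS over SC of each gene list (points) against the central 95% of 10000 random lists (grey bars), matched on level on the left and on GC content, length and level on the right; red points lie outside the bar. Of 31 lists 7 lay outside on the left, and of 30 lists 8 on the right, 7 of them on the same side in both.

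With the main measure, lists of invasion, adhesion and cell state were not apart from random lists under either matching, with the lung lineage list compared on level only. Of 18 measured invasion and adhesion genes, 3 were 2-fold higher and 2 lower (-0.08 relative to all genes, percentile 62.7). The receptor MET was at 3.45 and 26.5 TPM (log2 ratio 2.63), the protease MMP7 at 0.471 and 2.64 TPM (1.31) and the integrin ITGB1 at 55.1 and 133 TPM (1.26), whereas the adhesion molecule L1CAM was at 3.85 and 1.22 TPM (-1.13). Of 13 mesenchymal genes, 3 were 2-fold higher, CDH2, FN1, which encodes fibronectin (1.66), and CALD1 (1.23), while TAGLN had a log2 ratio of -0.66 (list median -0.33, percentile 5.97, but 0.13 as a mean of its members). For CDH2 the assembled locus was at 5.63 TPM in SC and 13.4 TPM in AS, and the log2 ratio in coverage was 1.26. Of 16 epithelial genes, OCLN and CLDN1 of the tight junction were 2-fold higher (both 1.20), followed by TJP1 (0.93) and EPCAM (0.82), with a list median of -0.27 (percentile 16.7). The TGF-beta response list (-0.16, percentile 33.7) held TGFBR2 (1.34), TGFB2 (0.98), TGFB1 (-0.71) and PMEPA1 (0.50). ERK output genes (0.29, percentile 92.8) were led by ETV1 (1.92), SPRY1 (1.44), DUSP5 (0.92) and DUSP6 (0.91). The ERK list stood at -0.08 among genes with a mean of at least 5 TPM and was apart in the assembled loci (0.52). Of 10 FOXO targets, 4 were 2-fold higher, PDK4 (1.47), TXNIP (1.47), TRIB1 (1.35) and CDKN1B (1.12), with a median of 0.59 (percentile 96.8). The FOXO list was apart with a pseudocount of 5 (0.38), in FPKM (0.54) and in coverage (0.81). In coverage matched on GC content, length and level it was not apart (0.27, percentile 90.8). Of 11 measured stem-like markers, 3 were 2-fold higher (0.45, percentile 86.7), HES1 (1.27), SOX2 (1.20) and JAG1 (1.00), followed by KLF4 (0.90). In coverage this list was apart (0.80). Only 5 of 24 lung lineage genes were measured, none past 2-fold (-0.02, percentile 36.8), with FOXA1 at 0.97, AGER at 0.42, NAPSA at -0.36 and ABCA3 at -0.30.

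Stress, death and immune lists were likewise not apart under either matching with the main measure. Of 20 genes of the ATF4 and amino acid response, 5 were 2-fold higher and none lower, among them PSPH (2.46 and 15.2 TPM, log2 ratio 2.23), SLC38A2 (1.72), MTHFD2 (1.19) and ATF3 (1.18), although the list median was -0.39 relative to all genes (percentile 8.20). That list was apart and lower among genes with a mean of at least 5 TPM (-0.45), in the coverage column (-0.59, percentile 0.56; -0.38 when matched on GC content, length and level, percentile 0.060) and in the assembled loci (-0.48, percentile 0.23). As a mean of its members it stood at -0.09 (percentile 54.7). HSP90AA1, the inducible HSP90, was at 345 and 1148 TPM (1.73), followed among heat shock genes by HSPD1 (1.26), DNAJB4 (1.17) and DNAJA1 (0.80), with a list median of -0.08 (percentile 88.9). The heat shock list had the other sign and was apart as a mean of its members (0.17) and in the assembled loci (0.33). None of 18 genes of the unfolded protein response passed 2-fold (-0.07, percentile 86.0). CALR was at -0.80, CRELD2 at -0.69, MANF at -0.68 and DNAJC3 at 0.66. None of 18 p53 targets passed 2-fold (-0.26, percentile 8.57), with GDF15 at -0.88, CCNG1 at 0.80, RRM2B at 0.78 and C12orf5 at 0.74. Of 18 apoptosis genes 1 was 2-fold higher and none lower. XIAP was at 0.79, DIABLO at 0.72 and CASP8 at 0.64, and the list median was -0.08 (percentile 37.3). Of 28 interferon response genes, 2 were 2-fold higher and 2 lower, IFI44L (1.47), OAS2 (1.08), OASL (-1.09) and IFIT3 (-1.08), with a median of 0.01 (percentile 65.3) that was -0.23 among genes with a mean of at least 5 TPM. Among NF-kB targets and cytokines (0.20, percentile 80.2), BIRC3 was 2-fold higher (1.52), ahead of NFKB1 (0.89), NFKBIA (0.83) and CXCL1 (0.79). NRF2 targets (-0.21, percentile 87.7) held TXNRD1 (1.17), GCLC (1.11), SRXN1 (1.02) and GCLM (0.96).

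Lists that mark RNA and library make-up, and other cell types, gave the following values. The list of 28 nuclear respiratory chain genes (-0.18, percentile 95.5) was apart in coverage and as a mean of its members, above its random lists in each. In coverage matched on GC content, length and level it was not apart (-0.01, percentile 44.7). None of these genes passed 2-fold, with SDHD at 0.85, COX6C at 0.76, ATP5A1 at 0.75 and ATP5O at 0.67. Of 37 ribosomal protein genes 1 did (-0.37, percentile 79.7), RPL30 at 1.04 in TPM and 0.18 in coverage, with RPS9 and RPL3 at -0.81 and RPL6 at 0.78. Replication-dependent histones (-0.28, percentile 8.74) included HIST1H3B at -1.41, HIST1H2AC at 0.75, HIST1H2BC at -0.47 and HIST1H3H at 0.46. The noncoding RN7SK was at 9.25 and 40.4 TPM (2.01), and RN7SL1 and RN7SL2 were both at 0.60. Fewer than 5 members of each list of another cell type were measured, and none of these passed 2-fold. They were 4 fibroblast markers, led by COL1A1 (-0.70), COL3A1 (0.63), LUM (0.33) and FBLN1 (-0.01), the leukocyte markers CD14 (-0.94) and CD68 (-0.49), the endothelial marker ESAM (0.25), and ENO3 (-0.93), UCHL1 (-0.33) and SYP (-0.03) of the neuroendocrine list. ENO3 is the muscle enolase rather than a neuroendocrine marker. The enolase ENO2, which is not among these measured members, was 2-fold lower (-1.17).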

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

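The values here come from assembled loci that overlap no annotated gene on either strand, which the comparisons above do not use, and they were looked at only after the data were seen. The value set against such a locus is that of the highest assembled locus overlapping it in the other library, also where that one reaches an annotated gene, as it did in SC for the loci on chromosomes 13 and 12 below. There were 585 such loci of at least 1 TPM in SC and 682 in AS. Of these, 10 reached 20 TPM in AS and at least 2 times the level of SC, in GRCh37 coordinates. The most abundant lay on chromosome 13 from 109917438 to 109923466, at 367 TPM in AS and 172 TPM in SC (109 TPM outside genes), and a locus on chromosome 16 from 35036717 to 35037097 stood at 162 and 64.9 TPM. Loci on chromosome 12 (113828002 to 113829416), chromosome 4 (136088642 to 136088922) and chromosome 18 (26273844 to 26274221) stood at 59.5, 44.4 and 36.8 TPM in AS against 24.4, 21.3 and 7.72 TPM in SC; the chromosome 12 locus had no locus outside genes in SC. Another locus on chromosome 16 (4357108 to 4358227) was at 22.6 and 5.41 TPM, and one on chromosome 2 (64304321 to 64304565) at 20.6 and 3.46 TPM. Loci on chromosome 9 (97305761 to 97305999), chromosome 5 (100321003 to 100321202) and chromosome 14 (35010060 to 35010904) were at 42.6, 25.6 and 23.9 TPM in AS and were not assembled in SC. In the other direction, by the same rule with the libraries exchanged, 1 locus was lower in AS, on chromosome 8 (115018099 to 115254164), at 66.9 TPM in SC and 0.911 TPM in AS. No explanation was tested for these loci.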

How the results depend on the processing

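The settings with the coverage column, the assembled loci, and matching or residuals on GC content, length and level were chosen after seeing the data; the others were planned. The cause was not tested for any value in this part unless stated. Genes at least 2-fold higher in AS (2251) numbered 727 with a pseudocount of 5, 760 with a mean of at least 10 (fewer genes tested), 1188 in FPKM, 1253 centred on the median, 1067 after trimmed mean scaling and 586 as residuals, and 4668 at 1.5-fold (a wider threshold). Genes lower in AS (297) numbered 501 with a pseudocount of 0.1, 70 with 5, 86 with a mean of at least 10, 194 among protein coding genes (fewer genes tested in both), 696 centred, 855 after trimmed mean scaling, 481 in assembled loci, 489 as residuals and 1033 at 1.5-fold. The setting of protein coding genes also rescaled the TPM of each library to the same sum over these genes. The FPKM setting applied the filter and the pseudocount to FPKM. Both counts stayed within 1.5 times with no filter, the largest row of a symbol and the coverage column. SET stayed higher in all 8 alternatives, with 0.64 as a residual. The seed shift stayed outside its matched range in all 6.

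Of the 31 lists, 31 kept their side of the central 95% with 5 bins, with matching on level and length, with random lists of protein coding genes and with the largest row of a symbol. The YAP and TAZ targets fell inside as a mean (0.34). The following lists lay outside only in the setting named. Described targets did so with a pseudocount of 0.1 (0.70), as a mean (0.63) and in assembled loci (0.86; matched on GC content, length and level 0.62), PP2A subunits in coverage (0.47), PP2A modulators with a pseudocount of 5 (0.24), ERK output in assembled loci (0.52; matched 0.45), and FOXO targets with a pseudocount of 5 (0.38), in FPKM (0.54) and in coverage (0.81). So did the ATF4 response with a mean of at least 5 (-0.45), in coverage (-0.59; matched -0.38) and in assembled loci (-0.48; matched -0.38), heat shock as a mean (0.17) and in assembled loci (0.33), stem-like markers in coverage (0.80; matched 0.58), and oxidative phosphorylation as a mean (-0.10) and in coverage (-0.18). Oxidative phosphorylation lay above its random lists there, although its values are below 0. Relative to their random lists, genes of fatty acid synthesis changed sign to -0.38 when matched on GC content, length and level, and to -0.41 in coverage, but lay inside in assembled loci (-0.33). Inside the central 95%, the median relative to all genes changed sign for the mesenchymal list as a mean (0.13), ERK output with a mean of at least 5 (-0.08), apoptosis as a mean (0.05), the unfolded protein response in assembled loci (0.01), the lung lineage with a pseudocount of 5 (0.05), heat shock with a pseudocount of 5 (0.01) and a mean of at least 5 (0.01), and the interferon response, which was below 0, by most with a mean of at least 5 (-0.23), and also with a pseudocount of 5, as a mean, in coverage and in assembled loci. Mitochondrial transcripts, apart in each of these, were at 0.09 with a pseudocount of 5, 0.08 with a mean of at least 5, 0.00 in FPKM and 0.07 in assembled loci. Of the 24 named genes, BCAS3 (0.11) and TSPAN14 (0.33) changed sign in assembled loci, and MZT2A (0.048) and EXTL3 (0.017) in coverage. The other 22 kept their sign in coverage, and in assembled loci 21 did, with SFT2D3 listed at 0 there in both libraries. The signs of MZT2A and EXTL3 in coverage depend on its TPM scale. Their deposited coverage was lower in AS, at 48.4 in SC and 45.5 in AS for MZT2A, and 3.11 and 2.86 for EXTL3. Read counts are not given in the sources used here, so no limit set by depth was computed.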

Other observations

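The test of SET in the coverage column, the dependence on GC content as a topic and the set of genes in this paragraph were chosen after the data were seen. Among 8417 protein coding genes of at least 5 TPM in 1 library, 18 were at least 2-fold higher in AS in TPM, in coverage and in the assembled locus, and lay above the central 95% of their 200 nearest genes in each. They include UPF3B, a factor of nonsense-mediated decay (10.6 and 52.1 TPM, log2 ratio 2.20), the translation regulator EIF4G2 (81.5 and 327 TPM, 1.99), USP10 (9.17 and 37.9 TPM, 1.94), PSMC3IP (42.6 and 149 TPM, 1.78), the mitotic kinesin KIF18B (12.7 and 39.9 TPM, 1.58), BOD1, SLBP, E2F2, CTGF and MATR3. The cell cycle inhibitor CDKN2C (18.1 and 41.0 TPM, 1.14) and the inhibin subunit INHBB (9.04 and 23.4 TPM, 1.28) are in the same set. In the other direction 9 genes passed, among them FASN, ENO2, ALDOC, SLC16A3, TM7SF2 (whose assembled locus was listed at 0 in AS), the lactate dehydrogenase LDHD (28.4 and 8.08 TPM, -1.70), the collagen receptor MRC2 (84.1 and 32.9 TPM, -1.33), PGLS of the pentose phosphate pathway (143 and 60.4 TPM, -1.23) and the protease inhibitor SPINT1 (47.5 and 21.1 TPM, -1.13). The 3 measures come from the same reads, so passing in all 3 is not independent support. For CTGF the TPM and the assembled TPM were the same, at 49.7 in SC and 122 in AS. Without the rule of nearest genes, 831 genes were 2-fold higher and 28 lower in all 3 measures. By its definition, a central 95% leaves some genes outside.

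The relation of the log2 ratio to transcript GC content ran across the whole range of GC content in coding genes. Assembly of transcripts in pieces in 1 library would not leave it in the coverage column, where rho was -0.70, even though 13.8% of coding genes of at least 5 TPM held 2 or more assembled loci in SC and 10.4% in AS. Release from control through the 3' UTR alone was predicted to leave little partial correlation with the GC content of the coding sequence. That correlation was -0.23 given 3' UTR GC content and length. It cannot exclude such release, because the 1 annotated 3' UTR taken per gene may differ from those used in these cells. The 3' UTR also held a part, with -0.31 for its GC content given that of the coding sequence and 0.26 for its length, so a contribution through it stays open. GC-dependent recovery of RNA or of library fragments in 1 library may account for it, since noncoding genes showed the trend too, with a rho of -0.24 over 2319 genes. These were the measured genes not typed as protein coding, without those of the mitochondrial genome. Pseudogenes were not left out and may share reads with coding genes, so this set is not fully separate evidence. An effect of the treatment on transcripts of low GC content stays open, because each group is 1 library.

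SET was higher in AS, which is the direction expected of a transcript released from the microRNA if AS lowers its activity, a step that the labels do not spell out. Reads shared with SET pseudogenes do not account for it, with a log2 ratio of 1.32 for SET and these rows together, and neither does the division of coverage among transcripts, with 1.37 in the coverage column. The GC content, length and level of SET may account for it, since SET lay at percentile 94.5 of its 200 nearest genes. A specific effect on SET stays open, as its ratio exceeded the median of those genes by 0.64.

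Genes with a miR-494-3p seed match were higher in AS. The base composition of their 3' UTRs may account for most of this, since ATGTTTC lay only at percentile 74.6 among 7-base sequences of the same composition. Under matching on level, length and GC content of the 3' UTR the shift exceeded the matched median by 0.02, at percentile 98.8, and the upper end of the matched range (0.44) by less, so the part that these leave over is small. A small effect through the seed stays open, as does base composition that the bins did not capture.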
